A study of Mus musculus with 12 samples.

How the data were processed

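The series labels describe 12 samples of polyA RNA from RelA-deficient NIH3T3 cells that carry a RelA-DsRed fusion, in 4 groups of 3 (IL-1, LPS, PAM and media), after 2 h in microfluidic devices. Per the labels' protocols, cells were passaged at most 20 times, detached and lysed with detergent, and reverse transcription was run on the lysate without RNA extraction, followed by 10 cycles of pre-amplification and a tagmentation library kit. The labels mention no molecular identifiers, so counts are reads rather than molecules, and limits based on counts cover counting error only. Reads from such libraries come from along the transcript, so longer transcripts yield more of them.

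Each table holds raw counts per Entrez gene ID, as deposited, with no normalization. Per the submitters' processing notes, CASAVA, STAR and featureCounts were used with genome build mm10; versions, annotation, strand setting and the handling of multi-mapping reads are not given in the sources used here. Per the file headers, each count column is named after the alignment file that was counted. Files were compared byte by byte and count by count. The 9 tables of the LPS, PAM and media samples were byte for byte that of IL-1 replicate 3 and carried its alignment name, so they were treated as copies of that 1 library and left out. The counts of those 9 samples were not analysed here. The tables of IL-1 replicates 1, 2 and 3 were distinct, each with its own alignment name.

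Before the data were examined, tests with edgeR's quasi-likelihood method had been planned for each stimulus against media, for each pair of stimuli, for the overall difference among the 4 groups and for the mean of the stimuli against media, with gene list tests, overlaps of calls and 115 combinations of result and alternative setting. With 1 group left, none of these had a comparison to make. Fitted to the copied tables, contrasts among LPS, PAM and media would compare 1 library with itself, and those of IL-1 would compare its 3 libraries with copies of replicate 3. The settings reported instead were chosen after the files had been seen.

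Gene symbols, types and positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 is based on, by Entrez ID; 25275 of 27179 IDs matched. IDs without a symbol took 2.14% ± 0.17 (SD, n = 3) of the counts and stayed in the totals. CPM were computed from the total count of each library, which ranged from 17254518 to 18578859. At these totals, a count of 0 in 1 library allows up to 3 counts, or 0.161 to 0.174 CPM, and 0 in all 3 libraries together allows 0.0556 CPM. A gene was called detected at 1 CPM or more in each library. TMM and relative log expression factors (edgeR 4.0.16, R 4.3.3) lay between 0.98 and 1.02. The common coefficient of variation is the square root of edgeR's common dispersion, with 1 mean per gene, over 11784 genes kept by filterByExpr. On negative binomial counts simulated around the real means of those 11784 genes with coefficients of 0.05, 0.1 and 0.2, it returned 0.0498, 0.100 and 0.199.

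The 16 gene lists and 4 marker lists were fixed before the data were examined; the symbols Ctgf and Cyr61 were older names of Ccn2 and Ccn1, which the list also held. For each list, the log2 ratio of each library to the mean of the other libraries, log2(CPM + 0.5), was summarised as the median over detected members and placed among 10000 random lists, each member replaced by 1 of the 200 genes nearest in mean CPM. These percentiles describe these libraries and are not p-values over replicates. Lists with fewer than 3 detected members were not tested, which left 17 lists. Libraries of 11224 genes were simulated with 200 genes shifted in 1 library. Lists of 20 shifted genes exceeded the 97.5 percentile in 99.0% of draws at 1.2-fold and in 100.0% at 1.5-fold. With no shift 8.0% did, more often than the nominal 2.5%, so percentiles near that limit are not read as differences. At each shift, the 100 lists came from the same 200 genes of 1 simulated data set, in which genes varied independently. The simulation therefore gives no error rate for the real lists, whose members may vary together. Exon and transcript lengths and GC content were taken from GENCODE M21 and were known for 98.4% of the detected genes. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.

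The rule for named genes relied on calls between groups. Its 9 genes fixed by name are all given. For the rest it could not be applied and was replaced by the 4 members of each list with the highest mean CPM, the 10 rows with the most counts and the 5 genes with the largest spread at 5 CPM or more. This replacement was set after the data, gene values included, had been seen. All other named genes, among them members at or near 0 and the neighbours of Mdm2, were also chosen after their values were seen. Values of 1 member of the interferon-stimulated list are not reported here; it is left out of the plot of list members and kept in the counts and medians of the list. CPM compare a gene between libraries; between genes they also depend on transcript length, so genes are given in order of CPM, and that order per kb of merged exons is stated for the NF-κB and chemokine lists.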

Results

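RNA was sequenced from NIH3T3 cells, an immortalized mouse embryonic fibroblast line, that lacked endogenous RelA and carried RelA fused to the fluorescent protein DsRed. RelA is the p65 subunit of NF-κB. The samples were labelled as cells kept for 2 h in microfluidic devices with IL-1β (0.2 ng/mL), LPS (100 ng/mL), PAM (0.2 ng/mL, not spelled out further) or media, with 3 samples in each of the 4 groups. LPS, a bacterial cell wall lipid, signals through TLR4, and the cytokine IL-1β through its own receptor. The stated purpose was to compare the responses to the 3 stimuli.

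Only the IL-1 group could be described. The tables of all 9 LPS, PAM and media samples were identical to that of IL-1 replicate 3, in the counts of all 27179 gene IDs and in the total of 18578859. The header inside each of the 9 named the alignment of IL-1 replicate 3. Between the IL-1 libraries themselves, 1.01% to 1.10% of the genes with a mean count of at least 10 had equal counts, and 2.08% would be equal between repeated Poisson draws from 1 library. The 10 identical tables were therefore counted as 1 library of the IL-1 group. No stimulus was compared with media or with another stimulus, and no fold change or p-value is given for any of them. What follows are transcript levels in IL-1-treated cells, which do not show whether IL-1 raised or lowered a gene.

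The 3 IL-1 libraries held 17254518, 18091073 and 18578859 counts, and 11224 genes reached at least 1 CPM (counts per 1e6 counts of the library) in each. Across these genes, the correlation of log2(CPM + 0.5) between libraries lay between 0.992 and 0.994 (Pearson) and between 0.993 and 0.996 (Spearman); genes are not independent replicates. The libraries differed by more than counting error, with a chi-square per degree of freedom of 13.7 between replicates 1 and 2, 9.42 between 1 and 3 and 5.42 between 2 and 3. The common coefficient of variation beyond counting error, estimated with edgeR, was 0.0907, and 0.0676 without replicate 1. All values below are means ± SD over these 3 libraries. The labels do not say whether the libraries came from separate cultures, so the SD may be technical.

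Rela, the gene of the reporter and of the deleted locus (Entrez 19697, chromosome 19, 5637442 to 5648134, GRCm38), had 641, 551 and 723 counts, or 35.5 ± 4.46 CPM. Counts per gene do not separate the DsRed fusion from transcripts of the deleted allele. The receptor for the stimulus, Il1r1 (chromosome 1, 40222480 to 40316201), was at 50.0 ± 1.63 CPM, and its co-receptor Il1rap at 63.5 ± 1.72 CPM. Tlr2, a receptor for bacterial lipopeptides (chromosome 3, 83836272 to 83841824), was at 133 ± 12.4 CPM, above Tlr4 (chromosome 4, 66827551 to 66846581) at 7.94 ± 0.571 CPM in all 3 libraries. Ly96, the partner of TLR4, was at 7.49 ± 0.561 CPM and Cd14 at 31.1 ± 4.60 CPM. Of 33 listed receptors and adaptors, 27 reached 1 CPM in every library, among them the shared adaptor Myd88 at 149.5 ± 8.44 CPM and the kinase Ripk2 at 129 ± 17.8 CPM. Il1rl1, the receptor for IL-33, stood far above the rest at 10589 ± 234 CPM. Cd36 had no count, which allows up to 0.0556 CPM over the 3 libraries together.

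Transcripts of the NF-κB family and its feedback inhibitors were present broadly, with 16 of 19 at 1 CPM or more in every library. Nfkbia, which encodes the inhibitor IκBα (chromosome 12, 55489409 to 55492647), was highest at 159.6 ± 12.3 CPM, followed by Nfkbie at 153 ± 15.1 CPM, Nfkb2 at 112 ± 15.4 CPM, Cyld at 108 ± 6.81 CPM and Nfkb1 at 102 ± 7.95 CPM. Tnfaip3, which encodes the ubiquitin-editing inhibitor A20 (chromosome 10, 19000910 to 19015410), was at 50.9 ± 4.30 CPM. Per kb of merged exons, Nfkbia and Nfkbie stayed first and second, while Cyld moved from rank 4 to rank 8. Tnip3 was at 0.928 ± 0.210 CPM, Bcl3 at 0.688 ± 0.221 CPM, and Nfkbid had no count.

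Secreted inflammatory factors ranged from abundant to not detected. Ccl2, a monocyte chemoattractant (chromosome 11, 82035577 to 82037452), was at 499.9 ± 36.6 CPM, Cx3cl1 at 443 ± 79.1 CPM, the neutrophil chemoattractant Cxcl1 (chromosome 5, 90891245 to 90893121) at 169.6 ± 8.37 CPM and Ccl7 at 66.2 ± 6.89 CPM. This order was the same per kb of exon. Of the 19 chemokines, 12 reached 1 CPM in every library. Cxcl2 and Cxcl3, relatives of Cxcl1, were near the floor, with 2, 1 and 0 counts of Cxcl2 and 1, 0 and 7 counts of Cxcl3 in replicates 1 to 3, and Ccl3 had no count. Of 24 cytokines and growth factors, 13 reached that level, including the macrophage growth factor Csf1 at 637 ± 82.0 CPM and the EGF-family ligands Ereg at 118 ± 5.68 CPM, Areg at 67.8 ± 6.61 CPM and Hbegf at 64.9 ± 4.58 CPM. Il6 (chromosome 5, 30013114 to 30019975) was low and spread widely, at 7.11 ± 2.77 CPM. Tnf, Il1b, Ifnb1 and Bmp2 had no count in any library.

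**Figure D1:**
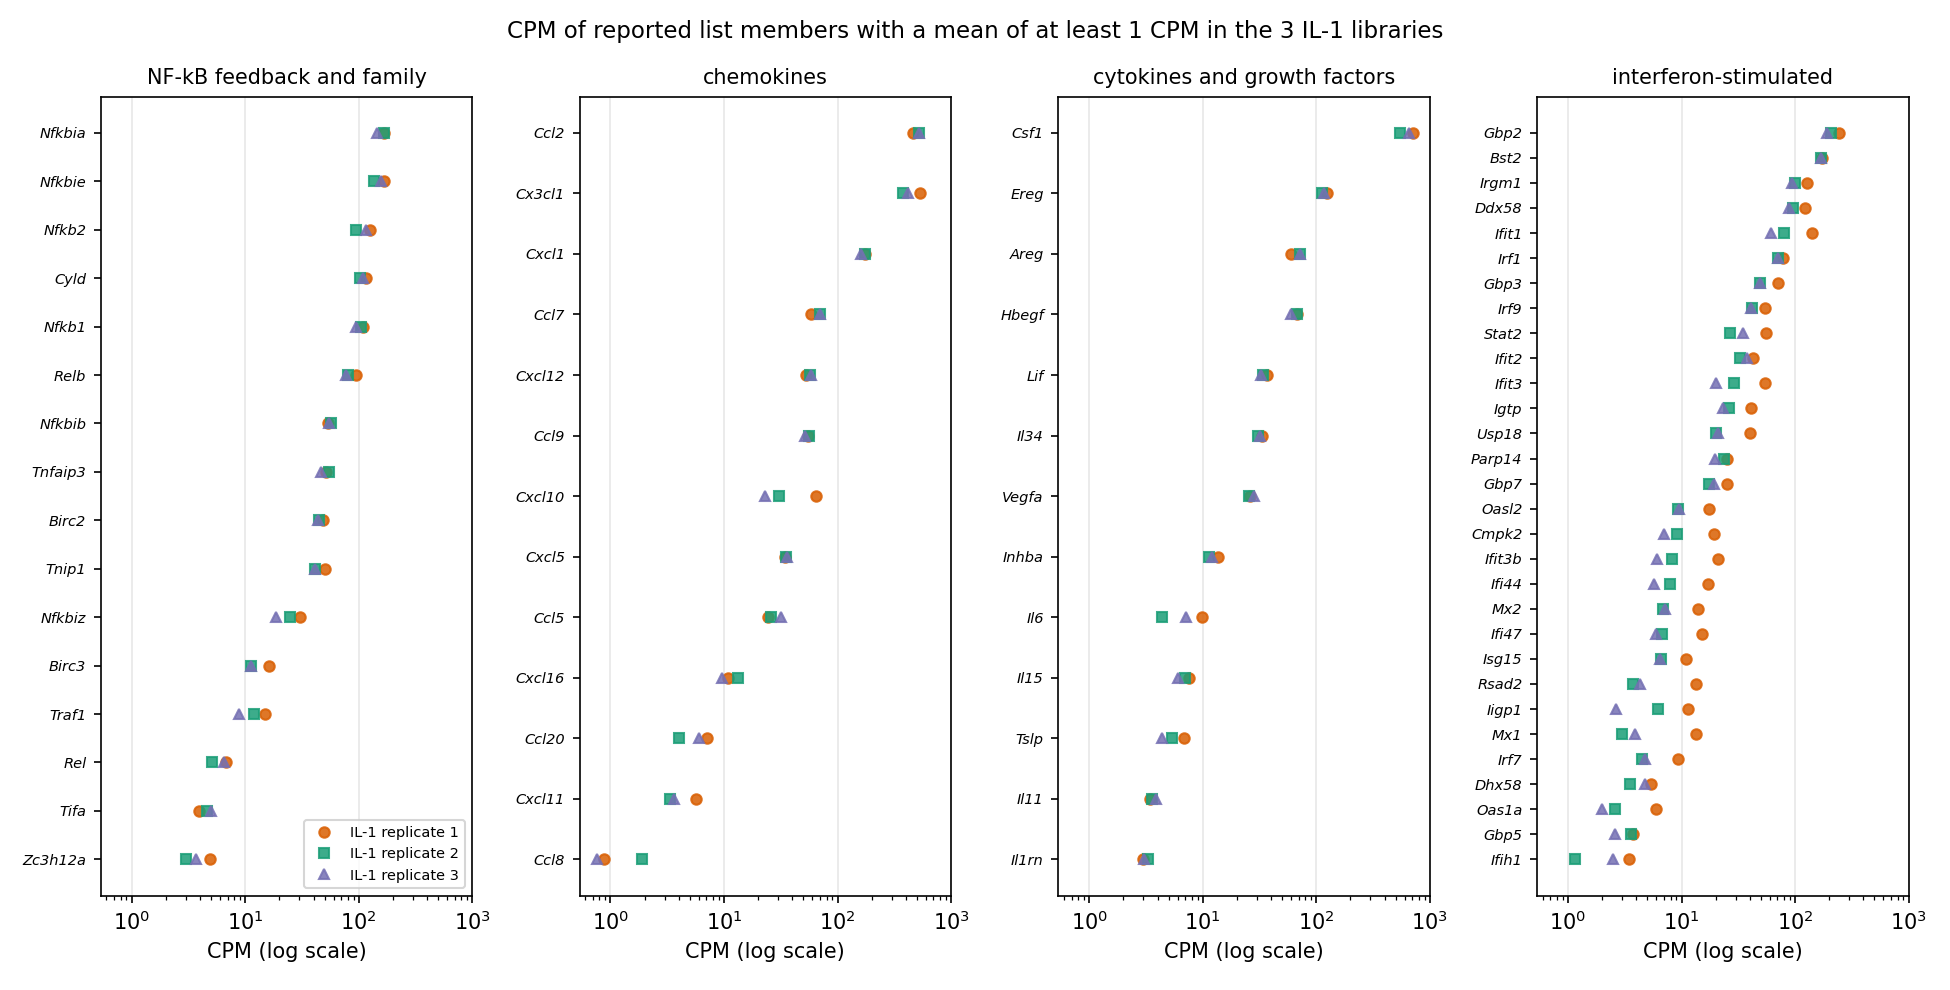
Each point is the CPM (log axis) of 1 gene in 1 of the 3 IL-1 libraries, for reported members of 4 gene lists with a mean of at least 1 CPM, sorted by mean. In the interferon-stimulated panel the points of replicate 1 lie to the right of both others for all genes plotted; in the other panels no library leads throughout.

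Interferon-stimulated genes were detected almost throughout the list and had the largest median difference between libraries of the 17 lists tested. Of 32 members, 31 reached 1 CPM in every library, with Gbp2, a GTPase, at 214 ± 28.6 CPM, Bst2, which tethers virions, at 171 ± 1.63 CPM, Irgm1 at 107 ± 16.8 CPM and Ddx58, which encodes the RNA sensor RIG-I, at 102 ± 18.6 CPM. All 31 were highest in replicate 1, against 45.7% of all 11224 genes. Ifit1 had 139.7, 79.5 and 61.1 CPM in replicates 1 to 3, and Mx1 13.3, 2.98 and 3.93. The median member was 1.77-fold higher in replicate 1 than in the mean of the other libraries (log2 ratio 0.83, members from 0.02 to 1.80), at the 100.0 percentile of 10000 random lists matched on expression. Between replicates 2 and 3 the median ratio was 1.03-fold. Interferon-responsive genes of other lists, picked after their values were seen, went both ways. Cxcl10 had 64.4, 30.7 and 22.9 CPM and Cxcl11 5.62, 3.32 and 3.61. Ccl5 had 24.5, 26.0 and 31.5 CPM, B2m 1298, 1585 and 1488, and Cxcl9 1, 9 and 13 counts. In the adhesion and antigen presentation list, which holds B2m, 10 of the 17 detected members were highest in replicate 1. Among them were Tap1 (30.1, 16.5 and 19.2 CPM), Tap2 (23.6, 14.7 and 19.6) and Nlrc5 (3.88, 2.27 and 2.53). Another 5 were highest in replicate 2 and 2 in replicate 3. The 5 genes with the largest SD of log2(CPM + 0.5) among those at 5 CPM or more were Mx1, Iigp1, Rsad2, Ifit3b and Rn7sk, a small nuclear RNA. The first 4 belong to the interferon-stimulated list. Reads of near-identical pairs such as Ifit3 and Ifit3b may be split by the counting.

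Among the other lists, the 4 low macrophage markers moved most, with a median 1.34-fold that of the other libraries in replicate 2 (percentile 99.6) and 0.755-fold in replicate 3 (percentile 0.70). Of 51 pairs of list and library, 5 lay in the outermost 0.1% of matched random lists on either side, and 3 of these were the interferon-stimulated list. Pairs of the same list depend on each other, since each library is part of the mean that the others were set against. The low values of the interferon-stimulated list in replicates 2 and 3 thus largely restate its high value in replicate 1. The remaining extreme pairs were the cholesterol synthesis list, 1.10-fold higher in replicate 3, and the cell cycle list, 0.912-fold in replicate 2. The NF-κB list had a median 1.14-fold that of the other libraries in replicate 1 (percentile 99.5) and 0.917-fold in replicate 3 (percentile 0.15), and the chemokines stood at percentile 29.3 in replicate 1 and 24.7 in replicate 3. The median of all 11224 genes lay 0.04 (log2) above the other libraries in replicate 1.

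**Figure D2:**
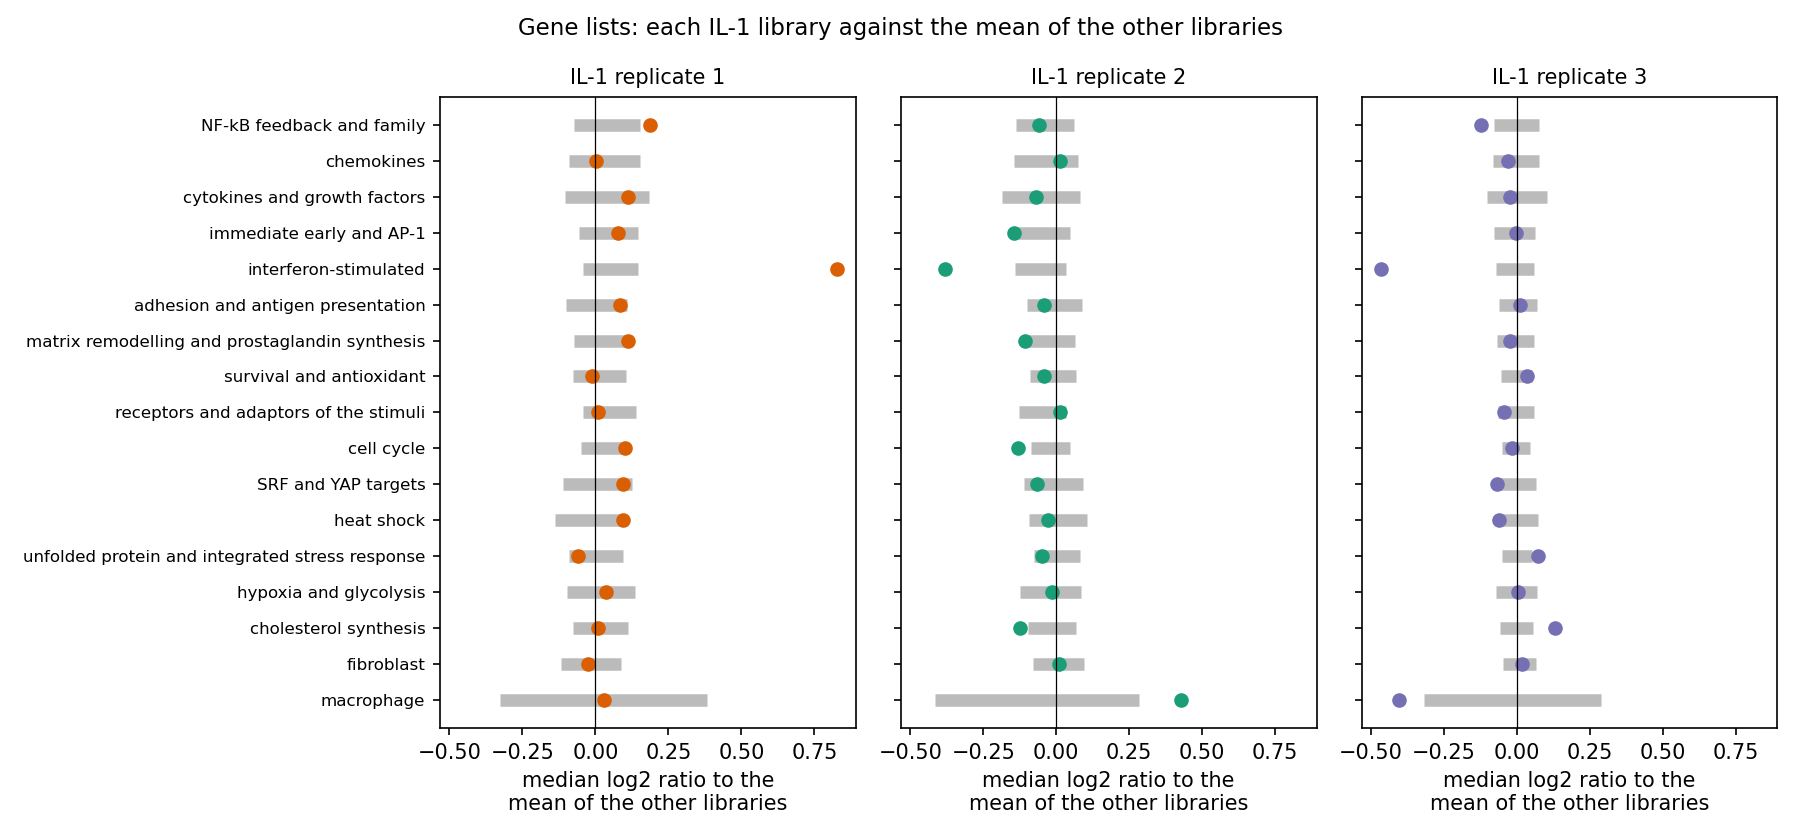
Points give the median log2 ratio of each gene list in 1 IL-1 library to the mean of the other libraries (x axis, log2), and grey bars the central 95% of 10000 random lists of the same size matched on expression. The interferon-stimulated list stands at 0.83 in replicate 1, -0.38 in replicate 2 and -0.47 in replicate 3. These values depend on each other, since each library is part of the mean that the others were set against.

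Immediate early transcripts included Myc at 549.6 ± 39.0 CPM, the AP-1 subunit Fosl2 at 219.8 ± 6.27 CPM, Ier3 at 179 ± 4.25 CPM and Klf6 at 138 ± 12.7 CPM, and 24 of 28 reached 1 CPM in every library. Fos was at 1.22 ± 0.0657 CPM, Egr1 at 9.85 ± 2.36 CPM and Jun at 20.5 ± 1.45 CPM. Nr4a3 had no count. Among adhesion and antigen presentation genes, 17 of 18 reached 1 CPM, with the adhesion molecule Vcam1 at 1939 ± 102 CPM, B2m at 1457 ± 146 CPM, Sdc4 at 931 ± 117 CPM and Cd44 at 593 ± 15.1 CPM. Icam1 was at 13.8 ± 0.872 CPM, and Selp had 1 count over the 3 libraries. H2-K1 and H2-D1, at 121 ± 5.52 CPM and 161 ± 8.46 CPM, share sequence, so their split is uncertain. Of 26 matrix and prostaglandin genes, 22 reached 1 CPM, with the protease inhibitor Timp1 at 1124 ± 99.0 CPM, Mmp2 at 318 ± 19.8 CPM, Timp3 at 244 ± 15.1 CPM and the cyclooxygenases Ptgs1 at 239 ± 9.89 CPM and Ptgs2 at 183 ± 20.6 CPM. Mmp13 was at 0.282 ± 0.155 CPM.

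Antioxidant and survival transcripts included the ferritin chain Fth1 at 7082 ± 620.0 CPM, Hmox1 at 1095 ± 65.2 CPM, Txnrd1 at 711 ± 44.0 CPM and Nqo1 at 393 ± 22.7 CPM, and 19 of 22 members reached 1 CPM. Mitochondrial superoxide dismutase Sod2 was at 206 ± 8.12 CPM. The near-identical Bcl2a1a, Bcl2a1b and Bcl2a1d had no count, which reads dropped as ambiguous would also give. All 16 stress response genes were at 1 CPM or more, with the serine synthesis enzyme Psat1 at 1736 ± 31.6 CPM, the chaperones Hspa5 at 1621 ± 59.5 CPM and Hsp90b1 at 1464 ± 79.1 CPM, and asparagine synthetase Asns at 1442 ± 42.2 CPM. Of 12 heat shock genes, 9 reached 1 CPM, including Hsp90ab1 at 4843 ± 205 CPM, Hspd1 at 773 ± 30.1 CPM, Hspa8 at 569 ± 34.1 CPM and Hspe1 at 313 ± 15.7 CPM. The near-identical, stress-inducible Hspa1a and Hspa1b were low and highest in replicate 1, with 28, 4 and 0 counts of Hspa1a and 23, 10 and 3 of Hspa1b. Without replicate 1 their means fell from 0.615 to 0.111 CPM and from 0.682 to 0.357 CPM.

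All 26 cell cycle genes were at 1 CPM or more, including Ccnd1 at 488 ± 10.9 CPM, Mcm6 at 350.5 ± 40.0 CPM, Cdk1 at 285 ± 3.15 CPM and Top2a at 243 ± 25.7 CPM. All 16 cholesterol synthesis genes were too, including Sqle at 820.2 ± 37.6 CPM, Cyp51 at 794 ± 22.3 CPM, Fdps at 522 ± 32.4 CPM and Hmgcs1 at 514 ± 36.6 CPM. Of 16 hypoxia and glycolysis genes, 15 reached 1 CPM, with Aldoa at 1380.2 ± 26.6 CPM, Ldha at 978 ± 32.3 CPM, Tpi1 at 885 ± 42.9 CPM and Eno1 at 420.4 ± 12.8 CPM. Of 14 matched targets of SRF and YAP, 13 did, with Tpm1 at 3804 ± 109.9 CPM, Acta2 at 414 ± 21.7 CPM, Vcl at 303 ± 11.9 CPM and Ankrd1 at 209.6 ± 8.26 CPM. All 13 mitochondrially encoded protein-coding genes were listed at 0 in every library, so no mitochondrial share could be given.

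Fibroblast markers were high, with Vim at 3162 ± 76.6 CPM, Sparc at 1484 ± 25.3 CPM, S100a4 at 1388 ± 154 CPM and Col1a2 at 1154 ± 9.66 CPM, and 13 of 14 at 1 CPM or more. Markers of other cell types were low. Of 11 macrophage markers, 4 reached 1 CPM, namely Lyz2 at 9.69 ± 2.70 CPM, Cd74 at 9.50 ± 1.70 CPM, Cd68 at 2.05 ± 0.945 CPM and Csf1r at 1.84 ± 0.379 CPM, while the pan-leukocyte gene Ptprc had 3, 0 and 6 counts in replicates 1 to 3. None of 8 epithelial markers reached 1 CPM, with Krt14 the highest by mean, at 0, 8 and 4 counts. Of 7 endothelial markers, only Egfl7 did, at 13.8 ± 0.649 CPM, and Pecam1 was at 0.485 ± 0.136 CPM.

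The row with the most counts was Entrez ID 100861531, which has no symbol in the gene table used, at 17891 ± 1602 CPM. It was followed by Il1rl1, the secreted matrix protein gene Spp1 at 9248 ± 497 CPM, Fth1, Lars2 at 6684 ± 283 CPM, Lgals1 at 6143 ± 778 CPM, the p53 inhibitor Mdm2 at 5712 ± 396 CPM, Eef1a1 at 5670.5 ± 384 CPM, Actb at 5591 ± 384 CPM and Rab3ip at 5095 ± 269.5 CPM. Reads of Fth1, Eef1a1 and Actb may be shared with processed pseudogenes, so these values are uncertain. These 10 rows took 7.97% ± 0.32 (SD, n = 3) of all counts. Mdm2 and Rab3ip lie near each other on chromosome 10, together with Yeats4 at 4739 ± 233 CPM, Cpsf6 at 3620.0 ± 454 CPM, the chaperonin subunit gene Cct2 at 1634 ± 24.8 CPM and the noncoding 4933412E12Rik at 2420.3 ± 134 CPM. Of the 20 protein-coding genes within 1 Mb of the start of Mdm2, 5 were at 1000 CPM or more, between positions 116905780 and 117710758, against 89 of 20983 protein-coding genes in the genome. Others in the same span were low, such as Frs2 at 48.2 ± 6.97 CPM, Cpm at 28.4 ± 4.82 CPM and Lyz2. These neighbours were chosen after their values were seen.

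**Figure D3:**
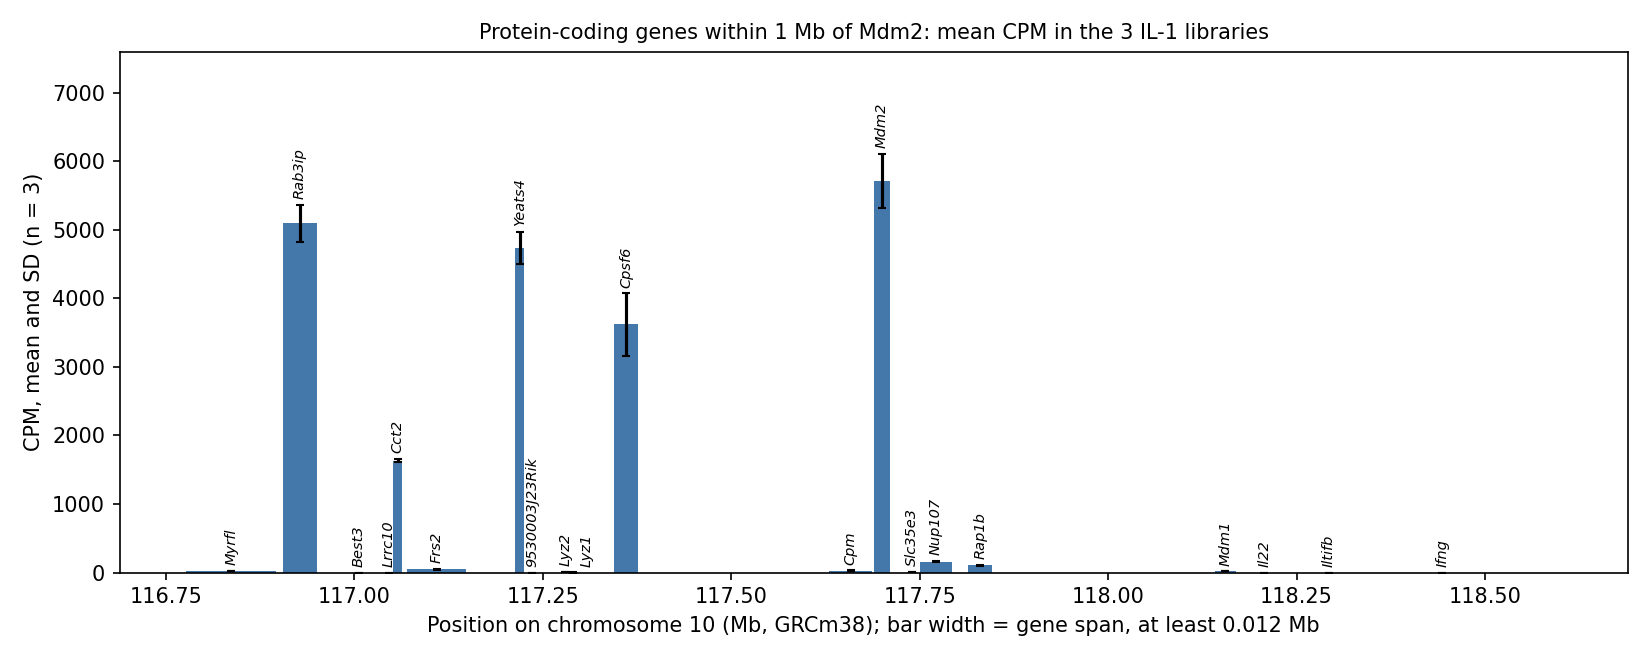
Bars give the mean CPM (y axis, linear from 0) of the 20 protein-coding genes within 1 Mb of Mdm2 in the IL-1 libraries, with SD as error bars (n = 3), at their position on chromosome 10 (x axis, Mb, GRCm38). Rab3ip, Cct2, Yeats4, Cpsf6 and Mdm2 exceed 1000 CPM and the other genes lie at 162 CPM or below.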

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

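All alternatives here were chosen after the data had been seen. No paired analysis was possible because only the IL-1 group had counts of its own, and none of the 115 planned combinations was run. TMM and relative log expression factors, and leaving out each library, left every count of detected genes, overall and per list, within 1.5 times its value, and so did a minimum of 0.5 CPM. A minimum of 2 CPM did so too, except for the macrophage markers, where 2 in place of 4 remained detected, by construction of the stricter level. For all 370 list members and other named genes with counts, each of the 1850 recomputed means (other factors, or 1 library left out) lay within 1 SD. Leaving out 1 of 3 libraries cannot move a mean by 1 SD, so only the other scaling factors test these values. The median of the interferon-stimulated list moved by less than the spread between its members with other factors, a pseudocount of 0.1 CPM, and without replicate 2 or 3. Its members ran from 0.02 to 1.80 in log2, so this bound is loose and says little about stability. The coefficient of variation ranged from 0.0676 without replicate 1 to 0.108 without replicate 3, so replicate 1 sets much of the spread. A 0.5 Mb window around Mdm2 held 3 genes at 1000 CPM or more in place of 5, since Rab3ip and Cct2 lie farther out. Depth limits what can be said of genes below 1 CPM, for which each library holds few reads.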

Other observations

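The tests reported here were chosen after the result was seen, except the regression on GC content and length and the median CPM per kb around Mdm2. The test of overlapping gene models was first written as such a median, over genes that overlap no other protein-coding gene; it left out none of the 20 genes and so tested nothing. It was replaced, after that was seen, by a count that takes in genes of any type. The test of macrophage RNA was changed more than once after the marker values had been seen. The median of the markers at 1 CPM or more came first and argued against macrophage RNA. That median together with the counts of the rarer markers then left it open. The sum of all markers replaced both, and its bound was also set after the data had been seen.

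The tables of the LPS, PAM and media samples equalled that of IL-1 replicate 3. Separate libraries that agree within sampling noise, whether or not the cells responded, would share few equal counts, as the IL-1 libraries did (at most 1.10% of genes with a mean count of at least 10), but 100.0% were equal in each of the 9 tables. All 9 headers name the alignment of IL-1 replicate 3, which is what 1 count table saved under 10 sample names would give. At which step this happened is open. Taken at face value, the tables would give no difference between LPS, PAM and media, while IL-1 against any of these groups would set 3 IL-1 libraries against copies of 1 of them.

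Interferon-stimulated genes were higher in IL-1 replicate 1 than in both other IL-1 libraries. A shift of all genes of like expression is argued against by the list's median, at the 100.0 percentile of matched random lists. GC content or transcript length is argued against too, since the median log2 ratio was 0.83 before and 0.85 after regression on GC, length and expression (percentile 100.0 after it). RNA from macrophages is argued against as the source of the whole excess: the summed CPM of the list was 482 higher in replicate 1 than in the mean of the other libraries, that of all 11 macrophage markers 1.55 higher (SD of the sums 4.81), and the 7 rarest of these together had 15, 4 and 9 counts in replicates 1 to 3. The labels name no difference between the 3 samples, so no biological explanation other than macrophage RNA was tested. An interferon response in replicate 1 may be followed up only as a hypothesis.

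Rab3ip, Cct2, Yeats4, Cpsf6 and Mdm2 were all at 1000 CPM or more within 1 Mb. The test chosen before its result was seen did not exclude chance clustering, and could not decide on it. The median CPM per kb over all 20 genes, silent ones included, exceeded 92.752% of 13658 other windows, short of the bound set for it. Those windows had the same width and at least as many protein-coding genes. The median of 5.14 lay between Frs2 at 5.51 and Cpm at 4.77 CPM per kb. It would be the same however far the 5 genes stood above these. No other of those windows held more than 2 genes at 1000 CPM or more, but this count was made afterwards and restates why the segment was singled out, so it tests nothing and chance clustering stays open. Reads counted for overlapping gene models are argued against because all 5 genes overlap no other counted gene with a position in the gene table, noncoding ones included; 4933412E12Rik begins at 116950562, just beyond the end of Rab3ip at 116950456. A gain of copies of parts of this segment in the cell line may be a candidate explanation, was not tested and needs DNA data, and no biological explanation was tested.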
